A study of Mus musculus with 4 samples.

How the data were processed

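Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 4 mouse cell populations with 1 library each. Per the labels, 50000 cells per library were lysed, transposed for 30 minutes at 37 °C and amplified for 12 PCR cycles. The libraries came from mouse embryonic fibroblasts (MEF), induced pluripotent stem cells (iPSC), v6.5 embryonic stem cells (ESC), and fibroblasts taken through the first step of conversion to neural stem cells with the factors Oct4, Sox2, Klf4 and Myc (OSKM). In that step doxycycline and 4-hydroxytamoxifen were given from day 1 to day 9 with a JAK1 inhibitor at 0.5 µM, and cells in which a Nanog-driven Cre recombinase had switched on tdTomato were sorted; they are called the intermediate here. The sample title of the intermediate gives day 9 and its source field day 6, and the protocol text matches day 9. The labels give the strain of MEF and iPSC as A12 (Mbd3 flox/-), that of the intermediate as B6/129 with a Col1a-OSKM transgene and that of ESC as v6.5. The strain label is thus the same for MEF and iPSC and differs in every other comparison. The labels do not say how far the backgrounds behind differing labels overlap.

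The submitters' processing notes name CASAVA 1.8.2, Bowtie2, Picard, MACS 1.4.2-1 and the mouse build mm10, without roles, and parameters are not given in the sources used here. The deposited files are 1 peak list per library with start, end, summit position and height, per the file headers. The height is a whole-number signal per peak that the authors' processing wrote, with a minimum of 5 in each list. Nothing in the files scales it to library size. Read totals were not used here, and the depth behind each list is unknown. Heights served to rank peaks within a list and to describe them. Heights of several libraries given side by side below are unscaled and do not measure differences in accessibility. A score per peak had been assumed when the comparisons were set, and the height was used in its place. Neighbouring peaks in a list were most often 10 bp apart and never overlapped, so accessible stretches had been divided into sub-peaks by a program that is not named in the sources used here. How the authors called and divided peaks sets the number of regions in every list, and a site without a listed peak is called closed below without any measurement of its accessibility.

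Peaks on the 19 autosomes and the X chromosome were compared. Peaks of the 4 lists that shared at least 1 bp were merged into union regions, and a region was open in a library if it held a peak of that library. Regions open in iPSC and ESC and closed in MEF are called pluripotent regions, and regions open in MEF and closed in iPSC and ESC are called MEF-only regions. A region was gained in the intermediate if it was open there and closed in MEF, and lost in the opposite case. Jaccard indices are the bases covered in both lists over the bases covered in either. Gene positions came from the RefSeq genes of GRCm38.p6, the assembly that mm10 names, whose table as used here has no strand. Both ends of a gene therefore stood for its start site, and regions were assigned to the nearest protein-coding or listed gene within 100 kb, measured to the gene body. All 205 genes of 12 lists matched the table. The enhancer windows were set from start sites with strands taken from general knowledge. The count of regions at each list was ranked among 10000 random lists of the same size, as a description of these libraries. Random lists were matched on quintiles of the number of regions per gene. The matching does not extend to the libraries in which those regions were open. A list with many MEF regions thus has fewer regions to gain than its random lists, and one with few has more.

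With 1 library per group there was no replicate check, no test was run and no p-value is given. Shares carry Wilson 95% intervals, which cover counting error over regions or peaks only. The gene lists, the comparisons and most alternatives were set before the data were examined; joining peaks at most 10 bp apart, leaving out heights under 10 and taking the tallest of 4 height groups were added after. The genes named are members of the lists, with the tallest peak gained or lost at the gene, and for each direction of a comparison the 10 protein-coding genes with the most regions, some of which are not reported here. Other alternatives were an overlap of at least 50% of the shorter peak, the taller 50% of each list, lists of equal length, peaks of 500 bp, distal regions over 1 kb from a gene end, a gene-end window of 2.5 kb and assignment within 20 kb. The 50% overlap was counted over single peaks and not merged regions. These were ESC peaks for the pluripotent share, MEF peaks for the MEF-only share and intermediate peaks for the share in no other list. A search for transcription factor motifs was not run, since it needs the genome sequence, which was not used here. The steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with bedtools 2.31.1 for the 50% overlap and matplotlib 3.10.9 for plots. They were tested on simulated data of 60000 sites, and each simulated share was recovered with a difference of 0 percentage points. Those sites were well separated and had no divided or missed peaks, so this checks the code and not the real shares.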

Results

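Open chromatin was mapped in MEF, in the sorted OSKM intermediate at the end of factor induction, in iPSC and in ESC, with 1 library each. The design asks whether cells on the way from fibroblast to neural stem cell pass through a pluripotent state. The comparisons below set the intermediate against both MEF and the pluripotent cells. The intermediate had been sorted for past activity of a Nanog-driven Cre, and no unsorted OSKM cells were profiled. Its likeness to pluripotent cells may thus owe in part to the sort, and the values describe sorted cells only. The lists held 157212 peaks in MEF, 133235 in the intermediate, 132875 in iPSC and 129533 in ESC on the chromosomes compared. They covered 74.1, 65.4, 72.2 and 67.9 Mb in that order, with median peak widths of 440, 471, 531 and 501 bp. Median heights were 30, 34, 39 and 32. The 4 lists merged into 256632 regions, of which 18048 were open in every library. In those shared regions, 63.9% of which lay within 1 kb of a gene end (Wilson 95% interval 63.2 to 64.6), median heights were 87 in MEF, 83 in the intermediate, 95 in iPSC and 92 in ESC. Of 21631 protein-coding genes, 64.3% had a peak within 1 kb of an end in MEF, 62.3% in the intermediate, 65.3% in iPSC and 67.2% in ESC. Genes with such a peak in the other 3 lists lacked it in 5.38% of cases in MEF, 5.74% in the intermediate, 3.02% in iPSC and 0.726% in ESC.

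The intermediate shared more accessible sequence with the pluripotent cells than with the fibroblasts. Its Jaccard index was 0.317 with ESC and 0.265 with iPSC, against 0.214 with MEF. The iPSC and ESC lists resembled each other most, at 0.466, and MEF reached 0.191 with iPSC and 0.226 with ESC. Of the regions open in the intermediate, 38.3% (38.0 to 38.6) were open in ESC, 36.3% (36.0 to 36.6) in iPSC and 28.3% (28.0 to 28.6) in MEF. Regions that the intermediate shared with MEF were mostly shared with the pluripotent cells too, since 82.4% of them were open in iPSC or ESC. Away from gene ends the index with MEF was 0.118 for the intermediate and 0.117 for ESC, so the order of these pairs differed there.

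The intermediate had peaks in some of the pluripotent regions, more often in the taller ones. Of 28782 regions open in iPSC and ESC and closed in MEF, the intermediate had a peak in 10315, which is 35.8% (35.3 to 36.4). Regions near gene ends were open more often, at 47.2% (45.5 to 48.9) against 34.4% (33.8 to 35.0) of distal ones. In 4 groups of equal size by ESC height, the share was 20.5% in the lowest, 27.1% and 35.8% in the middle ones and 59.9% (58.7 to 61.0) in the highest. For scale, the iPSC list held 53.5% of ESC regions closed in MEF and the intermediate list 26.8%. ESC regions that iPSC lacked were open in the intermediate in 20.5% of cases (20.1 to 21.0), and iPSC regions that ESC lacked in 10.0% (9.76 to 10.3).

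**Figure D1:**
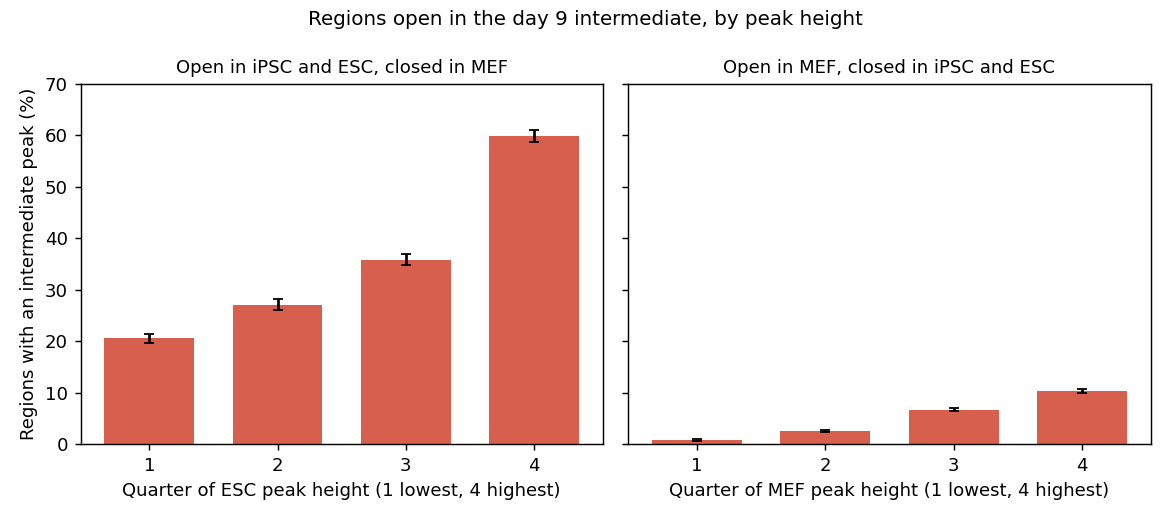
Share of regions with a peak in the intermediate (vertical axis, percent) for regions open in iPSC and ESC and closed in MEF, in 4 equal groups by ESC peak height, and for regions open in MEF and closed in iPSC and ESC, in 4 equal groups by MEF peak height; bars are shares over regions of 1 library each and error bars are Wilson 95% intervals. The left bars run from 20.5% to 59.9% and the right bars from 0.809% to 10.4%. Left regions needed peaks in both iPSC and ESC, right regions a peak in MEF. The left and right bars thus do not compare like regions.

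Some genes of the pluripotency list gained peaks at their ends in the intermediate. Of 30 pluripotency genes, 13 had an end peak in MEF, 21 in the intermediate, 27 in iPSC and 26 in ESC. The 9 that gained one were Nanog, Zfp42, Tdgf1, Fgf4, Lin28a, Sall4, Gdf3, Nr0b1 and Fbxo15, and Lefty2 lost one. Dppa4, Dppa5a and Dnmt3l had end peaks in iPSC and ESC and none in the intermediate or MEF. Esrrb and Prdm14 had an end peak in iPSC alone, Dppa3 in ESC alone and Nr5a2 in no library. At Nanog, a homeobox factor of the core pluripotency network, the promoter region on chromosome 6 from 122706741 to 122708060 had heights of 65 in the intermediate, 152 in iPSC and 105 in ESC. The intermediate had been sorted for past activity of a Nanog-driven Cre, so this gene was part of its selection. Tall gained peaks lay at Tet2, an enzyme that oxidises methylated DNA (chromosome 3, 133524161 to 133525710, heights 361, 89 and 84 in the intermediate, iPSC and ESC), and 3.97 kb from Tfcp2l1, a naive-state factor (chromosome 1, 118689141 to 118690731, heights 347, 117 and 46). Others lay 32.0 kb from Dppa3, between it and Nanog (chromosome 6, 122662301 to 122664480, heights 241, 102 and 130), and at Zfp42 (chromosome 8, 43306721 to 43307670, heights 140, 400 and 219). At the whole list, 66 of 132 pluripotent regions were open in the intermediate, 50.0% (41.6 to 58.4). This interval lies above the 35.8% over all pluripotent regions. Shares at other lists ran from 2 of 13 at Hox genes, 15.4% (4.33 to 42.2), and 9 of 27 each at imprinted and at mesoderm and endoderm genes, 33.3% (18.6 to 52.2), to 23 of 51 at fibroblast genes, 45.1% (32.3 to 58.6), 5 of 10 at housekeeping genes, 11 of 16 at trophoblast genes, 68.8% (44.4 to 85.8), and 4 of 5 at endothelial genes. The list gained 169 regions in the intermediate, more than 73.9% of random lists, or 119 after joining sub-peaks, more than 91.7%, and lost 89; 44 were lost with assignment within 20 kb.

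Known enhancers of the pluripotency genes had peaks in part. The window upstream of Nanog (chromosome 6, 122701489 to 122703489) had a peak in all 4 libraries, with heights of 118 in MEF, 317 in the intermediate, 159 in iPSC and 134 in ESC. Sox2, the partner of Oct4 on DNA, had end peaks in all 4 libraries. Its regulatory region 2 (chromosome 3, 34652995 to 34654995) had a height of 42 in the intermediate, 99 in iPSC and 82 in ESC. Its distal control region (chromosome 3, 34749995 to 34764995) held 2 peaks in the intermediate, at most 39 high, 11 in iPSC and 9 in ESC, and MEF had none in either window. Downstream of Klf4 (chromosome 4, 55462475 to 55482475) there were 2 peaks in MEF, 6 in the intermediate, 12 in iPSC and 9 in ESC. Both enhancer windows of Pou5f1, which encodes Oct4, had peaks in iPSC alone, with heights of 1330 and 491. In total, 4 of the 6 windows had a peak in the intermediate, 2 in MEF, 6 in iPSC and 4 in ESC. Pou5f1 is known to be active in ESC, so a missing peak in these lists is not read here as inaccessible chromatin.

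**Figure D2:**
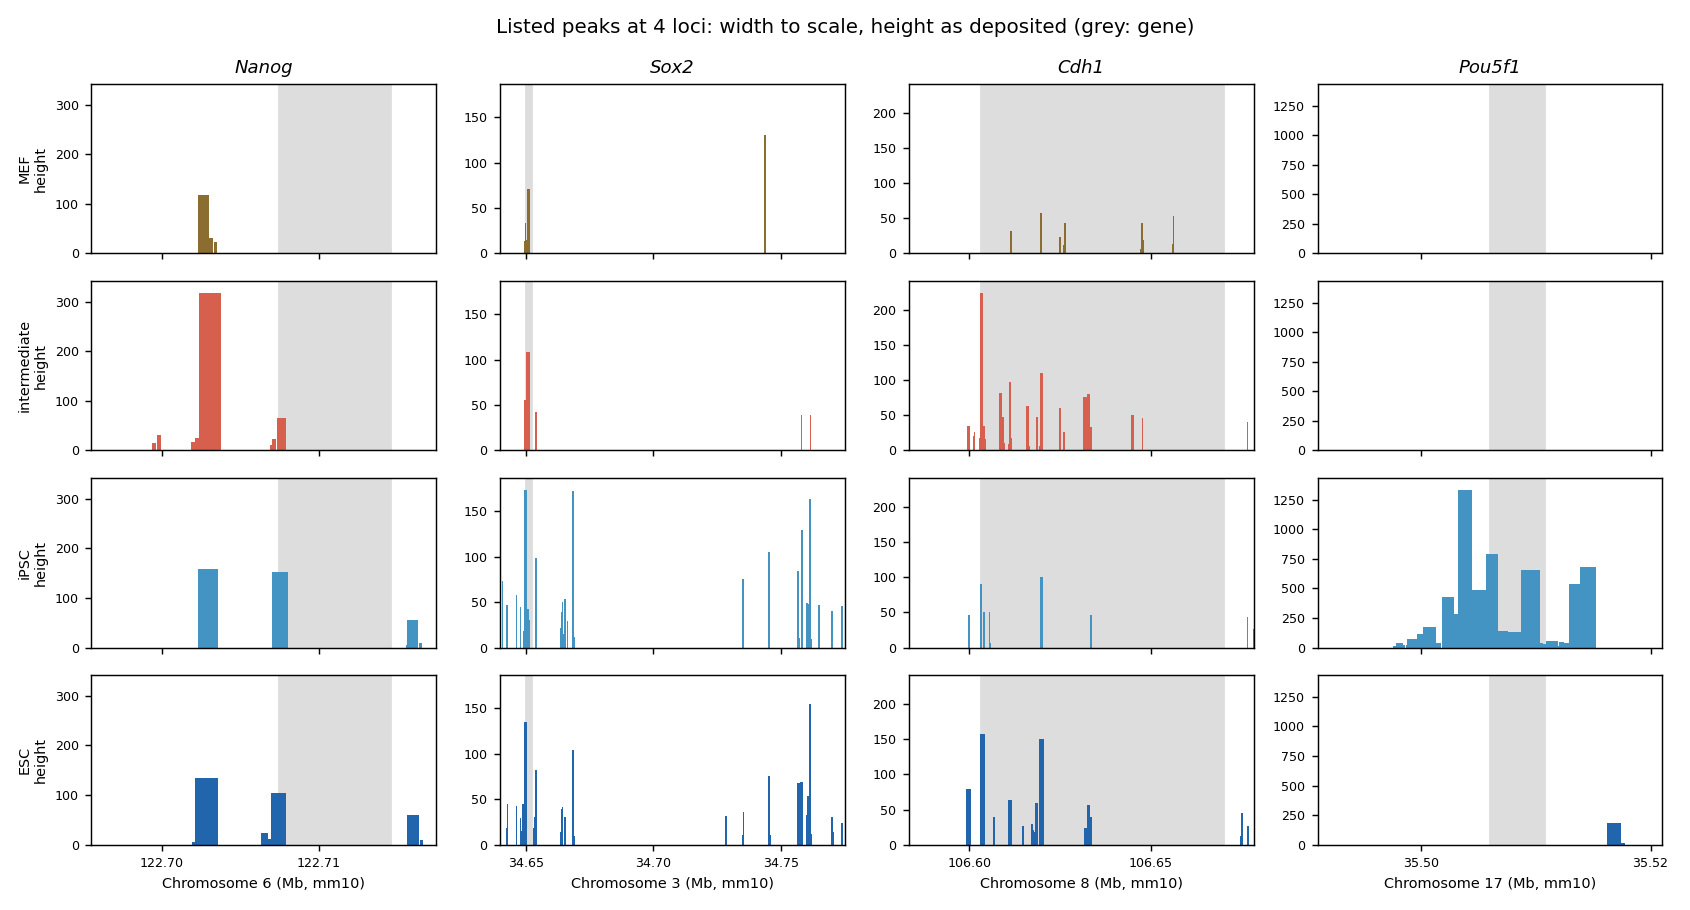
Listed peaks at Nanog, Sox2, Cdh1 and Pou5f1 in the 4 libraries; the horizontal axis is the position in Mb on the mm10 build, the vertical axis the peak height as deposited, bars span each peak and grey marks the gene. At the Nanog promoter the intermediate, iPSC and ESC have peaks of 65, 152 and 105 and MEF has none, and over Pou5f1 and its enhancer windows peaks are listed in iPSC alone, up to a height of 1330.

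Most fibroblast regions had no listed peak in the intermediate. Of 87566 MEF-only regions, 4473 had a peak in the intermediate, 5.11% (4.96 to 5.26), and the share was 0.809% in the lowest of 4 groups by MEF height and 10.4% in the highest. After joining sub-peaks the share over all MEF-only regions was 8.46%. With an overlap of 50% of the shorter peak it was 9.66%, counted over single MEF peaks and not over merged regions. A MEF-only region needed a peak in MEF, while a pluripotent region needed peaks in both iPSC and ESC. Their median widths were 431 and 960 bp, so the shares of these classes are not measured on like regions. Of all MEF regions, 21.7% were open in the intermediate, 21.6% in iPSC and 22.4% in ESC. Among 32 fibroblast and mesenchymal genes, 30 had an end peak in MEF, 20 in the intermediate, 21 in iPSC and 25 in ESC. The 20 include Col1a1, the locus named in the label of the OSKM transgene. The 10 that lost an end peak in the intermediate were Col3a1, Col6a3, Twist2, Postn, Pdgfra, Pdgfrb, Acta2, Tagln, Runx1 and Runx2, and 0 gained one. The list lost 573 regions and gained 118, where the median random list gained 208. MEF-only regions cannot be gained and made up 554 of its 898 regions, so this gap in part restates its make-up. After joining sub-peaks 289 were lost and 76 gained. Of its 554 MEF-only regions 21 were open in the intermediate, 3.79% (2.49 to 5.73), an interval that holds the share over all genes. Col5a1, a fibrillar collagen, lost 58 regions, Runx1, a transcription factor active in mesenchymal cells, lost 47 and Col1a1 lost 44. Tall lost peaks were those of the matrix protease Mmp2 (chromosome 8, 92847141 to 92847861, MEF height 231) and those 35.0 kb from the growth factor gene Tgfb2 (chromosome 1, 186586831 to 186587780, 199) and 89.1 kb from the matrix protein gene Postn (chromosome 3, 54480111 to 54481090, 170). The smooth-muscle genes Tagln and Acta2 lost peaks with MEF heights of 159 and 146. End peaks stayed listed in the intermediate for Vim, Fn1, Thy1, Snai1, Snai2, Twist1, Zeb1 and Zeb2. These genes had end peaks in iPSC and ESC too, so they do not mark a fibroblast state kept by the intermediate.

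Epithelial genes gained end peaks in the intermediate. Of 14 such genes, 3 had an end peak in MEF, 13 in the intermediate, 12 in iPSC and 14 in ESC. The 10 that gained one were Cdh1, Ocln, Cldn4, Cldn7, Esrp1, Grhl2, Ovol1, Rab25, Dsp and Crb3, and 0 lost one, while Krt18 had none. At Cdh1, the adhesion molecule E-cadherin, the tallest gained peak on chromosome 8 from 106602681 to 106604550 had heights of 224 in the intermediate, 90 in iPSC and 157 in ESC. Grhl2, an epithelial transcription factor, gained 21 regions, Epcam 14 and Cdh1 13. The list gained 86 regions, above 97.5% of random lists, and 52 after joining sub-peaks, above 86.5%, where housekeeping genes stood above 90.5%, and 20 of its 27 pluripotent regions were open, 74.1% (55.3 to 86.8). With a window of 2.5 kb, 6 epithelial genes had an end peak in MEF.

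Neural genes, the later target of the protocol, had end peaks in similar number in MEF and the intermediate. Among 20 neural stem cell and neuroectoderm genes, 15 had an end peak in MEF, 16 in the intermediate and 19 each in iPSC and ESC. Sox1, Pax6, Olig2 and Hes5 gained an end peak in the intermediate, and those that lost one included Fabp7 and Otx2. The genes that gained one had end peaks in iPSC and ESC too, so these gains do not mark a neural state. Of the 54 pluripotent regions at these genes, 25 were open in the intermediate, 46.3% (33.7 to 59.4), and of 65 MEF-only regions 0 were, with an upper limit of 5.58%. Both intervals hold the shares over all regions of the class, 35.8% and 5.11%. The list gained 99 regions, above 63.7% of random lists, or 48 with assignment within 20 kb. The tallest gained peaks lay 39.7 kb from Pax6, an eye and forebrain factor (chromosome 2, 105627951 to 105629180, heights 261 in the intermediate and 39 in iPSC, none in ESC), and 14.1 kb from the Notch target Hes1 (chromosome 16, 30081901 to 30082830, height 230, in the intermediate alone).

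**Figure D3:**
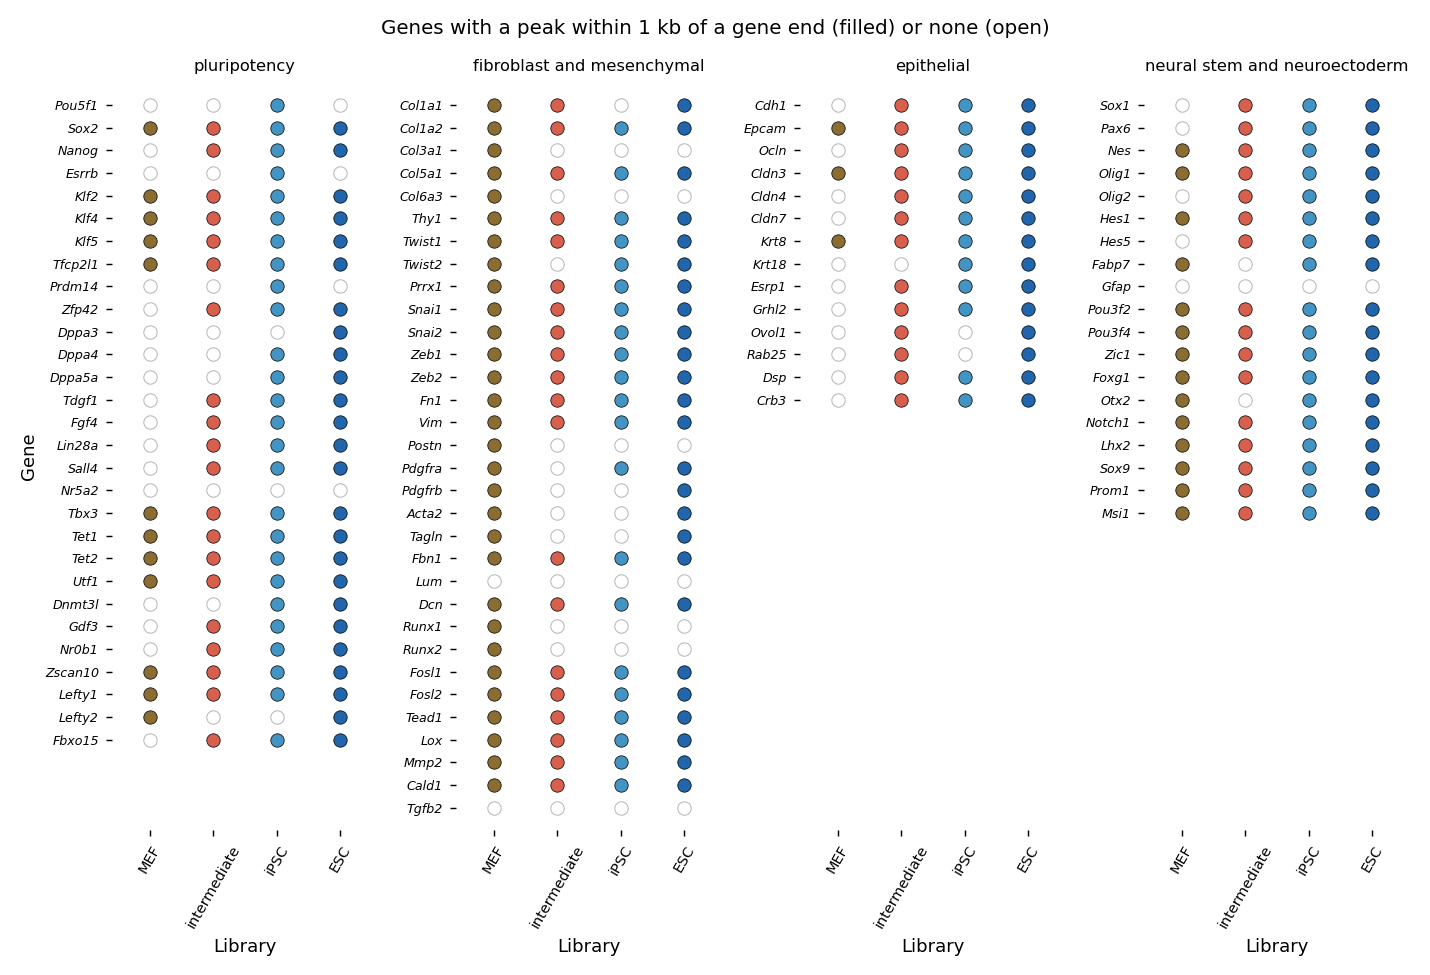
Selected genes of 4 lists (vertical axis) and libraries (horizontal axis); a filled circle marks a gene with a peak within 1 kb of either gene end and an open circle a gene without. End peaks in the intermediate are listed for 20 of 32 fibroblast and mesenchymal and 13 of 14 epithelial genes, and 3 of the epithelial genes have one in MEF.

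Genes of other lineages followed no single course. Mesoderm and endoderm genes had end peaks in 7 of 14 cases in MEF and 6 in the intermediate, where Mesp1 and Foxa2 gained one and Gata4, Gata6 and Kdr lost one; 9 had one in iPSC and 10 in ESC. Trophoblast genes had them in 5 of 7 cases in MEF, 3 in the intermediate, 3 in iPSC and 5 in ESC. Yet Elf5 and Tfap2c, factors of the trophoblast lineage, gained 19 and 14 regions in the intermediate, the tallest 38.8 kb from Elf5 on chromosome 2 from 103371901 to 103373291 with heights of 319 in the intermediate and 32 in iPSC. Germline genes had end peaks in 2 of 9 cases in MEF, 4 in the intermediate and 7 each in iPSC and ESC, and Ddx4, Sycp3 and Mael, open in both pluripotent libraries, had none in the intermediate. Of 16 pluripotent regions at germline genes 3 were open in the intermediate, 18.8% (6.59 to 43.0). Among markers of other cell types that a culture could hold, end peaks in the intermediate were listed at 2 of 6 myeloid genes, against 4 in MEF, and at 1 of 5 endothelial genes, as in MEF. The endothelial list gained 39 regions, above 80.7% of random lists with a median of 28, or 21 after joining sub-peaks. Before joining, Cdh5 gained 12 of them, Pecam1 9 and Tie1 7. The myeloid list gained 9, where the median random list gained 16. Of the myeloid list's 53 regions 23 were MEF-only, which cannot be gained. Housekeeping genes had an end peak in 11 of 12 cases in MEF, 12 in the intermediate, 10 in iPSC and 11 in ESC, and gained 44 regions, above 93.0% of random lists, or 27 after joining.

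Hox genes and imprinted genes had fewer end peaks in the intermediate than in MEF. Of 39 Hox genes, which pattern the body axis and record the position a fibroblast came from, 29 had an end peak in MEF, 17 in the intermediate, 22 in iPSC and 30 in ESC. Only Hoxb1 and Hoxd1 gained one in the intermediate and 14 lost one, among them Hoxa3, Hoxa5, Hoxa10 and Hoxb4. The Hox list gained 20 regions, where the median random list gained 56, and lost 108. Of its 206 regions 93 were MEF-only, which cannot be gained. After joining sub-peaks the list gained 11 and lost 46. Of 17 imprinted genes, 13 had an end peak in MEF, 9 in the intermediate and 12 each in iPSC and ESC. Meg3, H19, Nnat and Gnas lost one in the intermediate, and H19 had none in iPSC or ESC either. Dlk1 lost 34 regions, the tallest 33.8 kb away on chromosome 12 from 109417331 to 109418690 with a MEF height of 147.

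Many regions of the intermediate were found in no other list. These were 46706 of its 89826 regions, 52.0% (51.7 to 52.3), against 70.9% of MEF, 38.3% of iPSC and 26.1% of ESC regions measured the same way. They were distal in 90.7% of cases, had a median width of 431 bp and a median height of 30. Joining sub-peaks brought the share to 37.7%, and it was 20.8% in the tallest of 4 groups by intermediate height. The protein-coding genes with the most regions gained over MEF were Slc39a11, a zinc transporter, with 129, then Zbtb7c, Auts2, Mical3, Tbc1d1, Gpc6, Foxp1, Nav2, Zmynd8 and Tenm4, with 66 to 50. At Slc39a11 the tallest gained peak lay on chromosome 11 from 113558981 to 113559811, with a height of 223 in the intermediate and no listed peak in the other libraries. At Tenm4, a cell adhesion protein of neurons, it lay on chromosome 7 from 96203651 to 96205780 with heights of 364 in the intermediate, 114 in iPSC and 235 in ESC. The genes with the most regions lost from MEF included Gse1 with 97, Nav2 with 88, and Lpp, Zfp469, Zmiz1, Cacnb4, Auts2, Tns1 and Septin9 with 81 to 68. Lpp and Tns1 are components of cell-matrix adhesions. Nav2 and Auts2 stood on both sides, with 56 gained and 88 lost at Nav2 and 60 gained and 70 lost at Auts2, or 43 and 40 after joining sub-peaks. A count of regions per gene grows with the length of the gene, and after joining sub-peaks only 26 of the 60 counts of named genes stayed within 1.5 times, with 59 in place of 129 at Slc39a11, which had 85 with assignment within 20 kb.

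Slc39a11 and Zbtb7c also had the most regions when the intermediate was set against the pluripotent cells. Of the regions gained over MEF, 72.5% were in no other list and so count in both comparisons. Regions open in the intermediate and closed in iPSC and ESC were most numerous at Slc39a11, with 120 (79 within 20 kb), Zbtb7c with 64, Mical3 and Tbc1d1 with 54 each and Nav2 with 52, followed by Auts2, Gpc6, Foxp1, Ptprg and Cacna1a with 46 to 42. Regions open in iPSC and ESC and closed in the intermediate had lower counts per gene. There were 21 at Macrod2, 19 at Pde4d, 18 each at Magi2 and Ebf1, and 17 or 16 at Rabgap1l, Lrp1b, Gpc5, Elmo1, Cntn5 and Rbms3. This class held 18467 regions closed in MEF and 3841 open there, against 46706 and 4473 in the opposite class. Lower counts thus do not show a thinner spread over genes. By ESC height the tallest at these genes lay at Macrod2 (chromosome 2, 140676581 to 140677510, heights 193 in iPSC and 303 in ESC). Another lay at the phosphodiesterase Pde4d (chromosome 13, 109072891 to 109073911, heights 338 in iPSC and 262 in ESC). The one at Cntn5, a neural adhesion molecule (chromosome 9, 10540451 to 10541610), was lower than both by ESC height and had a height of 560 in iPSC. At 5 of these 10 genes the opposite count was as high or higher before joining, and at 0 of them after.

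The pluripotent libraries also differed from each other. Of iPSC regions 54.5% were open in ESC, and of ESC regions 63.3% were open in iPSC. Regions open in iPSC and closed in ESC were most numerous at Sox5, a transcription factor, with 60, Ptprn2 with 54, Pde4d and St6galnac3 with 51 each, and also high at Tenm3, Myo10, Robo1, Slit3 and Tiam1 with 44 to 40. At Slit3, a guidance ligand of the Robo receptors, the tallest lay on chromosome 11 from 35638611 to 35640060 with a height of 275 in iPSC and 35 in the intermediate. Regions open in ESC and closed in iPSC were fewer per gene, with 26 at Ptprg, 24 each at Atg7 and Magi2, 23 at Tmem132d, and 22 to 19 at Camta1, Pde4d, Tmem132c, Zfhx3, Pitpnc1 and Kazn. At some of these genes the opposite count was close or larger: Ptprg had 29 regions open in iPSC and closed in ESC, Magi2 22 and Pde4d 51. After joining sub-peaks Ptprg had 14 ESC regions against 23 and Magi2 14 against 17. The ESC count was 4 at Atg7 with assignment within 20 kb and 14 at Pde4d without heights under 10. The labels give these libraries different strains, so line and cell type vary together.

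The X chromosome held a larger share of the peaks in the pluripotent libraries than in MEF. Its share was 1.37% in MEF (1.31 to 1.42), 1.95% in the intermediate (1.88 to 2.03), 2.97% in iPSC (2.88 to 3.06) and 2.84% in ESC (2.75 to 2.93). The iPSC share was 2.17 times that of MEF, while the same ratios for the autosomes ran from 0.694 to 1.17. Within 1 kb of gene ends the shares were 2.00%, 2.17%, 2.92% and 2.57% in the same order, and among distal peaks 1.13%, 1.87%, 2.99% and 2.95%. The X-linked pluripotency gene Nr0b1 had end peaks in the intermediate, iPSC and ESC and none in MEF.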

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

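Both tests of the X share in this part were chosen after the shares had been seen. Peaks on the Y chromosome took no part in the comparisons, and their number exceeded that of the MEF list, 50, in iPSC with 539 and in ESC with 391, while the intermediate list held 34. End peaks at Y-linked genes were listed for 3 of 9 genes in MEF and in iPSC (Eif2s3y, Uty and Ddx3y), for 1 in ESC (Eif2s3y) and for 0 in the intermediate. Peaks on unplaced contigs, also left out, numbered 101 in the intermediate, 157 in iPSC and 102 in ESC against 68 in MEF.

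The X share of peaks was lowest in MEF and higher in iPSC and ESC, whose intervals overlapped and whose order turned at equal list length, with 2.80% and 2.84%. The number of X copies is argued against as the whole cause: the iPSC list, with end peaks at Y-linked genes, had an X share 1.01 percentage points above that of the intermediate, which has none, and MEF with the same 3 Y-linked genes as iPSC had the lowest share. A wider gain of distal peaks is argued against as the whole cause as well, since the ratio of iPSC to MEF shares was 1.46 among peaks near gene ends, though it was 2.17 over all peaks. A difference of cell state on the X chromosome may remain, as a hypothesis, and was not tested. Strain stays open for the intermediate and ESC, while MEF and iPSC carry the same strain label.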

How the results depend on the processing

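Joining sub-peaks, leaving out heights under 10 and taking the tallest of 4 height groups were chosen after seeing the data; the other alternatives were set before. The share of pluripotent regions open in the intermediate stayed between 33.8% and 37.9%, with 37.9% for the taller 50% of peaks, 34.4% for distal regions and 33.8% for a 50% overlap, and moved less than its interval in the other settings. The MEF-only share was 8.32% for the taller 50%, 6.17% at equal list length, 8.35% with 500 bp peaks, 4.89% distal, 9.66% with a 50% overlap, 8.46% joined and 5.73% without low peaks. The share in no other list was 40.9%, 51.4%, 38.6%, 60.3%, 38.9%, 37.7% and 48.1% in the same order, and 20.8% in the tallest of 4 height groups. Shares at a 50% overlap count single peaks and not merged regions, so they differ from the others in unit too. The cause of the differences between settings was not tested.

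The Jaccard index of the intermediate was 0.299 with ESC, 0.246 with iPSC and 0.198 with MEF for the taller 50%, 0.316, 0.265 and 0.212 at equal length, 0.242, 0.209 and 0.168 with 500 bp peaks, 0.320, 0.268 and 0.217 joined, 0.313, 0.263 and 0.212 without low peaks, and 0.221, 0.179 and 0.118 distal. The order ESC, iPSC, MEF held in each of these settings. A 50% overlap has no Jaccard value, since the index counts bases, and motif alternatives were not run.

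The taller 50% of peaks covered, by construction less, 52.2 Mb in MEF, 46.4 in the intermediate, 48.4 in iPSC and 47.1 in ESC. X shares for the taller 50% were 1.57% in MEF, 2.27% in the intermediate and 3.13% in iPSC. At equal length they were 1.84% in the intermediate and 2.80% in iPSC, and joined 1.61% in MEF, 2.37% in the intermediate and 2.96% in ESC, so MEF stayed lowest, while at equal length ESC, 2.84%, passed iPSC. Regions lost at pluripotency genes numbered 44 with assignment within 20 kb against 89. At fibroblast genes 289 were lost and 76 gained after joining, against 573 and 118. Counts of enhancer windows with a peak were equal at equal list length. Of the 60 named-gene counts, 57 stayed within 1.5 times with 20 kb, where Atg7 had 4 in place of 24, 60 at equal length, 59 without low peaks and 26 joined. No count or share could be set against replicate spread, and unknown depth limits what an absent peak shows.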

Other observations

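The tallest peaks found in the intermediate alone included 1 over 4931408C20Rik (chromosome 1, 26686681 to 26688650, height 747), and others 7.29 kb from Tex35 (chromosome 1, 157090491 to 157091850, 575), 21.1 kb from Slamf9 (chromosome 1, 172436361 to 172437510, 404), 1.28 kb from Adgrf2 (chromosome 17, 42745031 to 42746541, 327) and 2.32 kb from the gene of the Wnt co-receptor Lrp6 (chromosome 6, 134569231 to 134570500, 311). A peak with a height of 295 lay 97.6 kb from its nearest gene, the endoderm factor Foxa2 (chromosome 2, 148144561 to 148145650). These genes were chosen after their values were seen. At the right end of Col1a1 (chromosome 11, 94936224 to 94953042), the locus named in the label of the OSKM transgene, the intermediate had 4 peaks within 2 kb, up to a height of 138, while MEF had 5, up to 37, ESC 2, up to 45, and iPSC 0. Over the gene itself MEF had 32 peaks and the intermediate 3. Joined peaks over a height of 10000 numbered 11 in MEF, 12 in the intermediate, 11 in iPSC and 10 in ESC, and 8 of these sites were found in all 4 lists. The tallest lay on chromosome 1 from 24611211 to 24616690, with heights of 155962, 252435, 392147 and 297851.

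Of the tests below, those of the tallest joined regions and of a loss of tall peaks from the ESC list were chosen before their results were seen, and the others after. Regions of the intermediate in no other list made up 52.0% of its regions, or 37.7% after joining. Sub-peak splitting is argued against as the whole cause, since 12.5% of these regions (12.2 to 12.8) were parts of joined regions shared with another list. Weak peaks near the calling limit stay open. In the tallest of 4 height groups of joined regions, the share in no other list was 16.7% in the intermediate, 30.4% in MEF, 6.46% in iPSC and 1.35% in ESC. By the rule set beforehand, a share above that of ESC by more than both intervals would have argued against weak peaks. That rule was set aside after the values were seen. The comparison with ESC decided nothing, since iPSC held 71.4% of the joined ESC regions and no list held over 50.3% of the intermediate's. Strain or culture of the single intermediate library cannot be told apart from a passing cell state. There is 1 library of the intermediate, and no other group carries its strain label. A state of the intermediate with its own open sites may therefore be put forward only as a hypothesis.

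Pou5f1 (chromosome 17) lay in an unbroken block of 25 sub-peaks in iPSC, from 35497551 to 35515250, up to a height of 1330, and had no listed peak in MEF, the intermediate or ESC, whose lists had gaps of 91.0, 154 and 25.1 kb around the gene. A general loss of tall peaks from the ESC list is argued against, since 1 of the 159 tallest iPSC peaks near gene ends lacked an ESC peak, 0.629% (0.111 to 3.48), and that 1 is this block. Extra copies of the locus in the iPSC line could give such a block and stay open: it ranked 1 by length among 84416 joined iPSC peaks, but it had been noticed for its length. A test added after that rank was seen decided nothing. Of the block's sub-peaks 64% (44.5 to 79.8) were above the median height of the list, against 62.2% (54.1 to 69.8) in the 12 other long blocks. That share leaves out how tall they were. The block's median height was 117 and the list's 39, with no such median taken for the other blocks. A loss of peaks at this locus alone, and any biological explanation, were not tested.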
